A study of Mus musculus with 2 samples.

How the data were processed

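The series asked how macrophages that live in mouse pancreatic islets handle oxidants. Per the labels, islets were isolated from pools of 6 to 8 male C57BL/6J mice on chow diet. Live immune cells were sorted as negative for the dead-cell dye DAPI, negative for the epithelial protein Epcam and positive for the pan-leukocyte protein CD45. Droplet libraries that count the 3' ends of transcripts with unique molecular identifiers (UMIs) were made and sequenced to a planned 50000 reads per cell, with 3000 to 4000 cells targeted per condition. One pool was labelled 1 week and the other 12 weeks, and each time label had 1 library. The titles number the 2 libraries as replicates although their time labels differ, so the time label was used as the group. The labels do not say what the weeks count, such as time on the diet or age, so a ratio of 12 weeks over 1 week is a ratio between labels. The file labels also give each library its own experiment number, so time label and experiment go together.

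The deposited values are raw UMI counts per gene and barcode. Per the submitters' processing notes the reads were mapped to mm10 and counted with Cell Ranger, and the matrix headers give software version 3.1.0. How barcodes were chosen as cells is not given in the sources used here. Gene positions were taken from a GENCODE annotation of GRCm38, the assembly that mm10 names, by Ensembl gene identifier, and all 101 genes named by the rules below were matched.

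Barcodes were kept with at least 500 detected genes, at least 1000 UMIs and at most 10% mitochondrial UMIs. Scrublet, run in each library with an expected doublet rate of 0.02 through scanpy 1.11.5, called 1 doublet per library (0.0746% and 0.0571% of barcodes), so that it removed almost nothing and mixed droplets stayed in the data. Counts were scaled to 10000 per cell and log-transformed. A set of 2000 variable genes was chosen per library and combined, leaving out the tested list genes, mitochondrial, ribosomal, immunoglobulin and T cell receptor variable genes, and hormone and exocrine enzyme transcripts. The cells of both libraries were clustered together on 30 components and 15 neighbours with the Leiden method, at resolution 1 for classes and 0.6 for macrophage subsets, without batch integration.

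Clusters were named from fixed marker lists. A cluster needed at least 3 markers of a class among its 30 leading genes by fold. Macrophages made up most cells, so their markers rarely led a cluster by fold. Clusters without another name were called macrophage-like where the 9 macrophage markers were detected in over 60% of cells on average. That value was set after the detection shares were seen, and the clusters so named ranged from 70.8% to 88.3%. A cluster named endothelial-like from its own markers stood at 57.8%, and the B-, T-, dendritic- and endocrine-like clusters at 34.1% or lower. A macrophage subset was named only from its own fixed markers. Otherwise it kept its number.

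For each class or subset with at least 20 cells in each library, raw counts were summed per library. Sums were tested with edgeR 4.0.16 (R 4.3.3), using TMM scaling, filterByExpr, quasi-likelihood fits, the library as a block and Benjamini-Hochberg adjustment at 0.05. The contrasts were macrophages minus the unweighted mean of the other immune classes, and each subset minus the unweighted mean of the other subsets. Gene lists were tested with camera from limma 3.58.1 at a preset correlation of 0.01 between genes, and again with an estimated correlation. Members of a list were also adjusted over the list alone. A list member that is also a class marker was not tested between classes. The block takes out a difference shared by all profiles of a library. Every p-value therefore measures only how far differences between classes or subsets varied between these 2 libraries, each a pool of mice. The libraries carry different time labels, so this spread and every SD over them include any difference between the labels. The class and subset tests had 3 and 5 residual degrees of freedom. Subsets were clustered from the same cells that were then tested, without the list genes but with genes that vary alongside them, so subset p-values are smaller than those of groups known beforehand.

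The lists covered the glutathione system, the thioredoxin and peroxiredoxin system, superoxide dismutases and catalase, NRF2 target genes, selenoproteins and selenium handling, iron and heme handling, NADPH oxidase and nitric oxide synthase, MHC class II antigen presentation, lysosome and lipid handling, efferocytosis receptors, growth factors and regulatory cytokines, and glycolysis. Inflammatory cytokines and NF-kB response, interferon response, and immediate early and heat shock genes were listed for the time comparison and were set beside the others between classes too. Several genes stand in more than 1 list, so the lists are not independent.

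No test was run between the time labels. Macrophage counts were summed per library, and each gene's sum was divided by the macrophage total of its library (CPM), and the log2 ratio of CPM, 12 weeks over 1 week, was given with a 95% interval that covers counting error only. The median of each list was placed among those of 10000 random lists of the same size matched on mean expression. The random genes were drawn independently, so a list whose genes vary together can reach an extreme percentile. The percentile is no test of the time label. List members needed 50 UMIs over both libraries. Class shares carry exact Clopper-Pearson 95% intervals, again for counting error only, and a share of 0 is given with the upper limit that 3 cells would set. Hormone transcripts were given per class as a share of UMIs and also after thinning each cell to 2000 UMIs.

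The genes to be named whatever their result were Selenop, Slc40a1, Hmox1, Nfe2l2, Gpx1, Prdx1, Sod1, Sod2, Cat, Txn1, Cybb, Igf1 and Apoe. Between classes the rule added up to 3 called higher and 2 called lower per list by size of fold, and the 5 highest and 5 lowest called genes that were neither clustering genes nor markers and had at least 100 counts. Between subsets it added up to 2 higher and 2 lower per list. By time label it added the 10 highest and 10 lowest ratios among genes with at least 100 UMIs, leaving out mitochondrial, ribosomal protein and predicted genes, and 2 members per list. A few genes that these rules would name are not reported here. The groups, tests, lists, markers, naming rules, cell filters and the alternatives listed first below were fixed before the data were examined, except the 60% detection value that names clusters macrophage-like.

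On simulated counts with these sizes, the class test recovered 50.5% of genes changed by 1 log2 unit and 97.9% of those changed by 2, and called 3 of 4398 unchanged genes. The subset test recovered 90% and 98%, and called 4 of 8366. In both simulations the changed genes came from the better expressed genes, and any that fell below the count filter were left out of the percentages. No library difference, no other difference between classes or subsets and no macrophage RNA in other cells was simulated. These rates may therefore not carry over to the data. Intervals of the time ratio held the true value for 95.6% of unchanged genes, 95.2% at 1 log2 unit and 95.8% at 2.

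The alternatives were DESeq2 1.42.0 with its own size factors, no filter on low counts, no library block, each library alone, stricter cell filters (1000 genes, 5% mitochondrial UMIs), Scrublet calls kept, lower and higher clustering resolutions, each library clustered alone, other scalings of the time ratio, a minimum of 20 UMIs, and thinned cells. Chosen after the data were seen were removal of the 5% of cells with the highest Scrublet scores, removal of B-, T- and dendritic-like cells with at least 5 UMIs of C1qa, C1qb and C1qc, removal of macrophage subset 5 from the time ratio, a weighting of each macrophage subset to the same number of cells in both libraries, and a total without Gm42418 and AY036118, which overlap ribosomal RNA.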

Results

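The 2 libraries held immune cells sorted from mouse islets and counted by UMI, 1 pool of mice labelled 1 week and 1 labelled 12 weeks. The labels used here do not say what the weeks count. The 1-week library had 1551 barcodes and 12858754 UMIs, and the 12-week library 1867 barcodes and 12448628 UMIs, both under the 3000 to 4000 cells targeted. Filters left 1340 and 1752 barcodes, and 1339 and 1751 cells after the called doublets were removed, with medians of 7396 and 6827 UMIs and 1831 and 1732 genes per cell. The labels give male mice. Xist, the female-specific transcript, had 0 UMIs in both libraries, and the Y-linked Ddx3y had 720 and 922.

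Nearly all sorted islet immune cells were macrophages in both libraries. Macrophage-like cells made up 1220 of 1339 cells (91.1%, 95% interval 89.5 to 92.6) at 1 week and 1609 of 1751 (91.9%, 90.5 to 93.1) at 12 weeks. B-like cells made up 3.06% (2.21 to 4.13) and 1.77% (1.21 to 2.50), T-like cells 1.49% (0.915 to 2.30) and 3.20% (2.42 to 4.13), and dendritic-like cells 1.64% (1.03 to 2.48) and 2.11% (1.49 to 2.90). With 1 library per time label no difference in shares was tested, and the CD45 sort and the cell filters can set them. No cluster met the rule for monocytes, NK cells, neutrophils, plasma cells, mast cells, eosinophils, innate lymphoid cells, fibroblasts, acinar, ductal or erythroid cells. At the higher clustering resolution a neutrophil-like cluster of 1 cell at 1 week (0.0747%) and 14 cells at 12 weeks (0.800%) formed. Under the stricter cell filters B-like cells at 12 weeks made up 0.456%. With each library clustered alone no dendritic-like cluster formed at 1 week, which sets no bound on their share.

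The first comparison asked whether islet macrophages carry more antioxidant transcripts than the other immune cells of the same islets. Prdx1, a peroxiredoxin that reduces hydrogen peroxide, stood at 2981 ± 541 CPM in macrophages (SD, n = 2 libraries) against a mean of 1045 CPM over B-, T- and dendritic-like cells. Its log2 fold change was 1.82 (SE 0.28, edgeR quasi-likelihood test with Benjamini-Hochberg adjusted p = 0.0108). Of 18 NRF2 target genes tested, the oxidant-response genes driven by the transcription factor that Nfe2l2 encodes, 9 were higher and 0 lower in macrophages (16 and 0 adjusted over the list alone). Of 9 iron and heme handling genes 5 were higher and 0 lower (7 and 0 adjusted over the list alone). Of 10 glutathione genes 3 were higher and 0 lower (5 and 0 adjusted over the list alone).

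Among the NRF2 targets, the sulfiredoxin gene Srxn1 had a log2 fold change of 1.88 (SE 0.51), the biliverdin reductase gene Blvrb 1.79 (SE 0.26) and Pgd of the pentose phosphate pathway 1.58 (SE 0.35), with edgeR Benjamini-Hochberg adjusted p of 0.0468, 0.00873 and 0.029. At 1 week Srxn1 had 223.0 CPM in macrophages and 99.3, 205.5 and 100.4 in B-, T- and dendritic-like cells. At 12 weeks it had 473.3 CPM in macrophages and 0, 176.7 and 87.6 in those classes. In the glutathione system Glrx (1.62), Gclm (1.45) and Gclc (1.15) were higher, the latter pair encoding the enzyme that starts glutathione synthesis. In iron and heme handling the metal transporter gene Slc11a1 (1.94) and the ferritin gene Ftl1 (1.55) were higher. Of 9 thioredoxin and peroxiredoxin genes 4 were higher and 0 lower (4 and 1 adjusted over the list alone), among them Txnrd1 (1.44). Of 3 superoxide dismutase and catalase genes 2 were higher and 0 lower (2 and 0 adjusted over the list alone). These were the mitochondrial enzyme gene Sod2 (1.21, SE 0.26, 380.6 ± 24.5 against 201.2 CPM) and Cat (1.14, SE 0.30, 38.8 ± 0.684 against 21.1 CPM). The T-like cells of the 1-week library stood about as high as macrophages, at 396.4 CPM for Sod2 and 39.1 CPM for Cat. Of these 20 cells 10 held at least 5 UMIs of the macrophage genes C1qa, C1qb and C1qc. Their values may therefore include macrophage RNA.

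Several antioxidant genes did not pass the test. Hmox1, the heme-degrading enzyme, had a log2 fold change of 2.42 (SE 0.73, edgeR adjusted p = 0.0663), with 2837 ± 1362 CPM in macrophages (SD, n = 2) against 790.3. Values were 0.90 for Nfe2l2, 0.49 for the glutathione peroxidase gene Gpx1, 0.44 for Txn1 and 0.05 for Sod1, with edgeR adjusted p of 0.153, 0.16, 0.238 and 0.928. Dendritic-like cells stood above macrophages in both libraries for Nfe2l2 (628.4 and 666.0 against 452.0 and 580.1 CPM at 1 and 12 weeks). The same held for Gpx1 (466.9 and 473.2 against 445.0 and 370.7 CPM) and Sod1 (183.3 and 105.2 against 87.7 and 98.4 CPM). Gpx1 at 1 week and Sod1 at 12 weeks lay close in the 2 classes, on dendritic-like sums of 229166 and 285301 UMIs. Dendritic-like cells were not tested against macrophages alone. Of 11 selenoprotein genes 2 were higher and 0 lower (2 and 0 adjusted over the list alone), Txnrd1 and Selenop, the secreted selenium carrier. Selenop had a log2 fold change of 2.15 (SE 0.43, edgeR adjusted p = 0.0236) and 365.3 ± 0.517 CPM in macrophages. The T-like cells of the 1-week library stood as high at 367.0 CPM, but 50% of them held at least 5 UMIs of C1qa, C1qb and C1qc. That value may therefore include macrophage RNA. The iron exporter gene Slc40a1 and Igf1 were below the count filter and were not tested between classes.

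In GRCm38 Prdx1 (ENSMUSG00000028691) spans chromosome 4 from 116685544 to 116700822, Srxn1 (ENSMUSG00000032802) chromosome 2 from 152105516 to 152111376, and Hmox1 (ENSMUSG00000005413) chromosome 8 from 75093621 to 75100589. Sod2 (ENSMUSG00000006818) spans chromosome 17 from 13006846 to 13040063, Cat (ENSMUSG00000027187) chromosome 2 from 103453849 to 103485160, and Selenop (ENSMUSG00000064373) chromosome 15 from 3268547 to 3280508. The counts are sums over the whole gene, read from the 3' end.

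**Figure D1:**
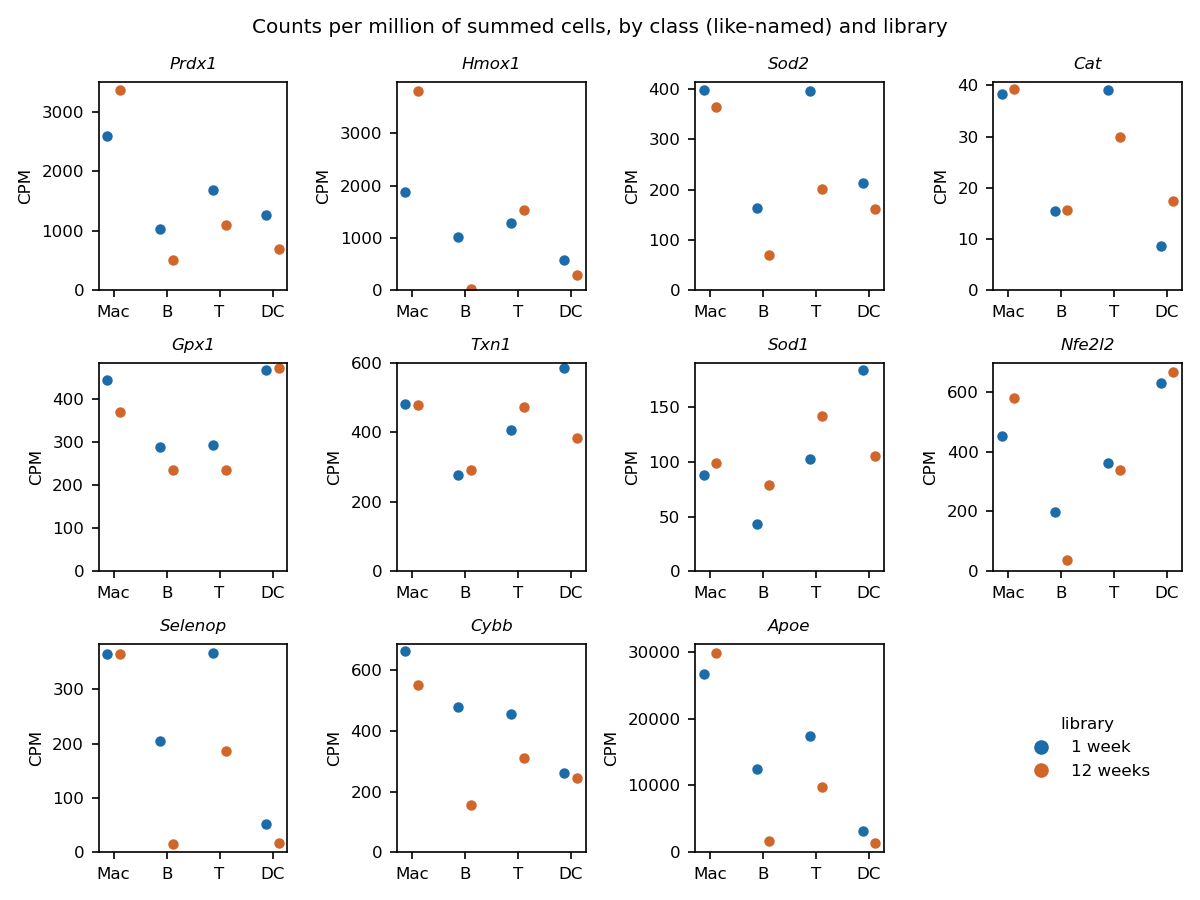
CPM of 11 named genes (vertical axes, starting at 0) in summed macrophage-like (Mac), B-, T- and dendritic-like (DC) cells, 1 point per class and library. Prdx1 in macrophages stood at 2598 and 3364 CPM, above every other point of its panel, while Sod1 overlapped between classes.

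Lysosomal and lipid genes were higher in macrophages for most members. Of 16 tested, 13 were higher and 0 lower in macrophages (16 and 0 adjusted over the list alone), led by the lipid carrier Apoe (2.70, SE 0.43, 28199 ± 2244 against 7628 CPM), the scavenger receptor gene Cd36 (2.24) and the lipid droplet gene Plin2 (1.85), with edgeR Benjamini-Hochberg adjusted p of 0.0129, 0.0264 and 0.0337. Of 4 efferocytosis genes, which serve the uptake of dying cells, 3 were higher and 0 lower (4 and 0 adjusted over the list alone), namely Stab1 (2.44), Itgb5 (2.18) and Axl (1.49). Of 15 inflammatory genes 6 were higher and 0 lower (10 and 0 adjusted over the list alone), among them Cxcl1 (3.30), Il1a (2.66) and Ccl3 (2.23). Of 5 growth factor and regulatory cytokine genes 2 were higher and 0 lower (4 and 0 adjusted over the list alone), Pdgfa (2.63) and Il10 (2.39). Of 16 immediate early and heat shock genes, which cell isolation can induce, 6 were higher and 0 lower (8 and 0 adjusted over the list alone), among them Hspa1a (2.83), Egr1 (2.10) and Atf3 (2.01).

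Of 11 MHC class II genes 5 were higher and 1 lower (7 and 1 adjusted over the list alone). H2-Eb1 (0.98), Cd74 (0.95) and H2-DMb1 (0.94) were higher, and H2-DMb2 had a log2 fold change of -3.07 (SE 0.44, 5.97 ± 0.784 against 93.9 CPM, edgeR adjusted p = 0.00873). Of 7 genes of the superoxide-generating NADPH oxidase and nitric oxide synthase 2 were higher and 0 lower (2 and 1 adjusted over the list alone), among them Cybb (1.11). None of 11 glycolysis and 11 interferon response genes passed edgeR's test, over all genes or adjusted over the list alone, with 0 and 0 called by DESeq2. At an unadjusted p under 0.05, 4 glycolysis genes were higher and 1 lower, and 4 interferon genes were higher and 0 lower.

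DESeq2 called fewer members higher in most lists, 6 of the NRF2 targets, 4 iron and heme, 2 glutathione, 3 thioredoxin and peroxiredoxin, 1 superoxide dismutase and catalase, 2 MHC class II, 12 lysosomal and lipid, 5 inflammatory, 4 stress and 1 NADPH oxidase gene. It called as many as edgeR for selenoproteins (2), efferocytosis (3) and growth factors (2). Counts of 0 lower members above held with it except in the NADPH oxidase list, with 1 lower. At an unadjusted p under 0.05, 1 thioredoxin and 1 NADPH oxidase gene were lower. The 5 highest called genes outside clustering genes and markers were Lilra5, Tmem37, Bhlhe41, Cxcl1 and Hspa1a. Lilra5, Tmem37 and Bhlhe41 had no counts in dendritic-like cells, so their fitted folds are no measure of size. Lilra5 stood at 90.4 ± 6.89 CPM in macrophages and 22.1 over the others, and Tmem37 at 36.1 ± 3.12 and 12.9, with 53.8 and 19.9 CPM in T-like cells. Bhlhe41 stood at 39.99 ± 10.04 and 21.4 CPM, and B-like cells held 40.9 and 62.8 CPM of it. The 5 lowest were H2-DMb2, Map4k1 (-2.57), Itpr1 (-2.49), Add3 (-2.29) and Uck2 (-2.16).

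**Figure D2:**
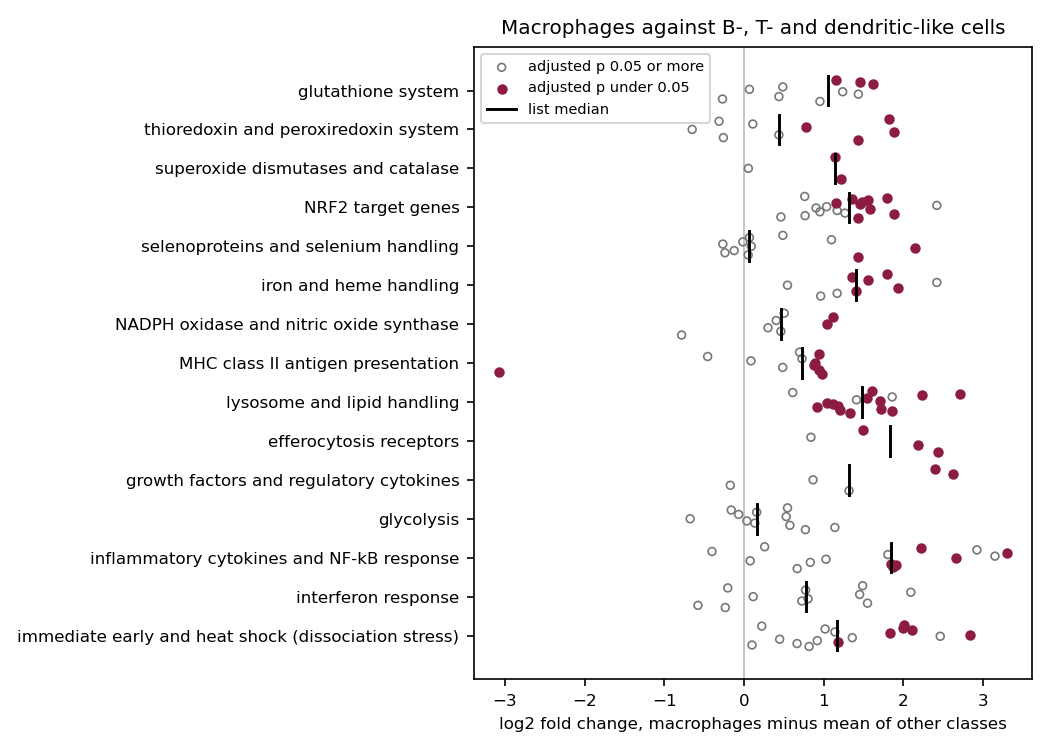
Log2 fold change of each tested member of the fixed lists (horizontal axis), macrophage-like cells minus the mean of B-, T- and dendritic-like cells, with filled points for edgeR adjusted p under 0.05 and a bar at the list median. Medians were 1.31 for NRF2 target genes, 1.48 for lysosome and lipid handling and 0.07 for selenoproteins.

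Over all 4598 genes tested, 333 were higher and 158 lower in macrophages, and 263 and 43 of these were neither clustering genes nor markers (edgeR, 8 summed profiles). Camera with a preset correlation called NRF2 target genes (median log2 fold change 1.31, adjusted p = 1.24e-06), lysosome and lipid handling (1.48, 8.48e-07), iron and heme handling (1.404, 0.000979), stress genes (1.16, 0.000979), inflammatory genes (1.84, 0.00335), glutathione (1.05, 0.00855) and efferocytosis (1.83, 0.0184). None of these calls held with an estimated correlation, where the smallest adjusted p was 0.46. Not called at the preset correlation were MHC class II (0.73, adjusted p = 0.0597), superoxide dismutases and catalase (1.14, 0.075), NADPH oxidase (0.46, 0.075), growth factors (1.32, 0.102), interferon response (0.77, 0.107), the thioredoxin system (0.44, 0.165), glycolysis (0.16, 0.205) and selenoproteins (0.07, 0.241). With an estimated correlation their adjusted p lay between 0.46 and 0.648.

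Macrophage transcripts were present in part of the other cells, unequally between the libraries. At least 5 UMIs of C1qa, C1qb and C1qc were found in 15 of 41 B-like (36.6%), 10 of 20 T-like (50%) and 5 of 22 dendritic-like cells (22.7%) at 1 week, and in 2 of 31 (6.45%), 16 of 56 (28.6%) and 4 of 37 (10.8%) at 12 weeks. At 1 week the B-like cells with them had a median of 18361 UMIs and those without 5540. Without these cells, a setting chosen after the data were seen, 852 genes were higher and 442 lower. With the 1-week library alone the NRF2 median was 0.70 and the iron and heme median 0.86, and with the 12-week library alone 2.13 and 2.38. With the called doublets kept, the T-like class had 19 cells at 1 week and left the fit, and 6 genes were higher and 50 lower.

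The second comparison asked whether antioxidant transcripts differed between macrophage subsets. In subset 4, with 420 cells, 9 of 19 NRF2 targets were higher than in the other subsets (12 adjusted over the list alone). Hmox1 stood there at 4670 ± 1250 CPM (SD, n = 2) against a mean of 2319 in the other subsets (log2 fold change 1.35, SE 0.12, edgeR adjusted p = 9.56e-09), and Srxn1 at 426.4 ± 181 against 294.9 (0.82, SE 0.14, edgeR adjusted p = 0.000405). Of 12 thioredoxin and peroxiredoxin genes 4 were higher in subset 4 (6 adjusted over the list alone). Its leading genes also held the metallothioneins Mt1 and Mt2 and heat shock genes such as Hspb1, Hspe1 and Dnaja1. Subset 4 was not found apart from subset 2 under the stricter cell filters or at the lower resolution. The cluster nearest to both was the same there, with an overlap of cells with subset 4 (Jaccard index) of 0.26 and 0.23.

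In subset 2, with 640 cells, 8 of 19 NRF2 targets were higher (8 adjusted over the list alone), led by Gclc (1.64, SE 0.19, 172.5 ± 51.9 against 67.1 CPM, edgeR adjusted p = 1.46e-07) and with Srxn1 at 0.87. Subset 2 was led by heat shock genes, among them Hspa1b, Hspa1a and Bag3. It was also higher in Vegfa (1.14), Slc2a1 (1.17), Hbegf (18.2 against 4.50 CPM), Mertk (12.3 against 4.69 CPM) and Fabp4 (7.60 ± 0.370 against 1.61 CPM), the last 3 at counts too low for their fitted folds to measure size. Of 7 NADPH oxidase genes 3 were lower (3 adjusted over the list alone), among them Ncf4 (-0.62) and Cyba (-0.44), and of 11 MHC class II genes 3 were lower (4 adjusted over the list alone), among them Ciita (-1.11). The methionine sulfoxide reductase gene Msrb1 (-0.55) and Abcg1 (-0.59) were lower. Ciita, the transactivator of MHC class II genes, was lower in subset 4 as well (-1.21) and higher in subset 6 (1.26).

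Subset 6, named interferon-responding-like from its markers, was higher in Cybb (0.77), Sod2 (0.52), Cd40 (1.57), Hk2 (1.39) and Pros1 (14.6 against 5.77 CPM), and lower in Pdgfb (-0.70) and Aldoa (-0.50). Mgst1 was called higher there, but with 3.17 CPM at 1 week and 22.6 at 12 weeks against 3.72 in the other subsets the call rests on the 12-week library. Subset 3 was higher in Sod2 (0.59), Spic (1.33), Cd36 (1.06) and Nqo1 (8.39 ± 6.06 against 2.39 CPM), and subset 1 in Sephs2 (1.11). Subset 7 had a median of 2968 UMIs and was led by Ins1, Iapp and Ins2. It was lower in Hmox1 (-1.43), Prdx1 (-1.18), Srxn1 (-1.46), Txnrd1 (-1.16), Gclc (-2.66), Slc7a11 (-1.69), Spic (-2.21), Lipa (-1.03) and Pkm (-0.85), and higher in Gpx1 (0.80). At the higher clustering resolution the folds of Prdx1, Spic, Srxn1 and Txnrd1 in subset 7 were 0.0733, 0.70, 0.16 and 0.29. Subset 5 had 209 cells at 1 week and 19 at 12 weeks and was left out of the fit.

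Of 126 list genes, edgeR called 7 higher and 4 lower in subset 1, 18 and 11 in subset 2, 16 and 0 in subset 3, 18 and 1 in subset 4, 13 and 3 in subset 6, and 5 and 13 in subset 7. In subset 3, 35 list genes had an unadjusted p under 0.05, and DESeq2 called 2 lower. Of 72 pairs of list and subset, camera at the preset correlation called 5. These were NRF2 targets in subset 4 (median 0.43, adjusted p = 0.00474) and subset 2 (0.44, 0.0493), the thioredoxin system in subset 4 (0.42, 0.0199), and NADPH oxidase (-0.27, 0.0493) and MHC class II (-0.15, 0.0391) in subset 2. None held with an estimated correlation, where the smallest adjusted p was 0.527 and 6 pairs had an unadjusted p under 0.05. The glutathione, superoxide dismutase, selenoprotein, iron and heme, lysosome, efferocytosis, growth factor and glycolysis lists were called in no subset. Without the library block, 1 list gene was higher in subset 4 and 7 in subset 2, and the higher NRF2 list in subset 4 was the 1 list still called. The overlap of subsets with those of other clusterings ranged from 0.03 to 0.91 (Jaccard index), and at the lower resolution the MHC class II median of subset 2 was 0.29.

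The third comparison set macrophages of the 12-week library against those of the 1-week library, with no replicate check. The macrophages of the 2 libraries lay in a different mix of subsets. Subset 4 held 68 of 1220 at 1 week and 352 of 1609 at 12 weeks, subset 2 held 210 and 430, and subset 5 held 209 and 19. Each list was therefore also computed with every subset weighted to the same number of cells in both libraries, a setting chosen after the data were seen. NRF2 targets stood higher at 12 weeks. Their median log2 ratio was 0.38 (95% counting interval 0.33 to 0.53), 17 of 19 members were above 0, and the median exceeded those of all 10000 matched random lists. With the same mix of subsets it was 0.31. Hmox1 had 1873 CPM at 1 week and 3800 at 12 weeks (log2 ratio 1.02, 1.00 to 1.04), Srxn1 223.0 and 473.3 (1.09), Gclm 146.2 and 268.7 (0.88), Prdx1 2598 and 3364 (0.37), and Nfe2l2 452.0 and 580.1 (0.36). The iron exporter gene Slc40a1 had a ratio of 1.35 (14.1 and 35.9 CPM) and Spic, a transcription factor gene of heme-handling macrophages, 1.14.

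The glutathione list had a median of 0.33 (0.20 to 0.49, percentile 99.93 of the random lists, 11 of 14 above 0). Its member Gstp1, at 2.04, stood higher at 12 weeks in other immune cells too (2.96). The lists of thioredoxin genes (-0.07, percentile 47.19), superoxide dismutases and catalase (0.04, 61.81), selenoproteins (0.04, 79.26) and iron and heme handling (0.09, 88.78, and 0.21 with the same mix of subsets) stood apart less from the random lists, the thioredoxin median turning to 0.0096 with the mean of per-cell CPM. Selenop (-0.00), Txn1 (-0.00), Cat (0.04), Sod1 (0.17), Apoe (0.16) and Sod2 (-0.13) had counting intervals within 0.3 log2 units of 0. Gpx1 had -0.26 (-0.32 to -0.20) and Cybb -0.27 (-0.32 to -0.22), and Igf1, on 78 and 84 UMIs, 0.04 (-0.42 to 0.50). Nqo1 had a ratio of 1.80 on 20 and 73 UMIs, Txnrd2 -0.72 and Selenoh -0.98.

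Interferon response genes had a median ratio of 0.77 (0.67 to 0.85, above all random lists, 13 of 14 above 0), led by Ifit3 (1.37) and Ifit2 (1.36). These leading genes rested on few cells. At 12 weeks 161 and 150 macrophages held a UMI of them, and 20 macrophages held 50% of the UMIs of each. The immediate early and heat shock list had 0.35 (0.28 to 0.40, percentile 99.99, 13 of 16 above 0), with Hspa1b at 1.09 and Dnajb1 at 0.99, and stood at 0.083 with the mean of per-cell CPM, at 0.13 with thinned cells and at 0.14 with the same mix of subsets, where Hspa1b and Dnajb1 had 0.54 and 0.54. Lysosome and lipid handling had 0.19 (percentile 98.91, 14 of 17 above 0), with Ctsl at 0.53 and Plin2 at 0.44. Efferocytosis receptors stood lower (-0.34, -0.42 to -0.12, percentile 2.3, 6 of 9 below 0), while Mertk had 0.88 and Cd300lb 0.73. Mertk had -0.38 with thinned cells. MHC class II (-0.11, percentile 35.48), inflammatory genes (-0.11, 29.06, and -0.27 with the same mix of subsets), NADPH oxidase (-0.12, 30.6, and 0.0055 with the same mix), glycolysis (-0.18, 10.38, and -0.10 with the same mix) and growth factors (-0.00, 60.16) lay within the random lists. Members with the widest ratios were Ciita (-1.17) and H2-DMb1 (-0.35), Il1a (-0.98) and Nfkbiz (-0.68), Rac2 (-0.33, and 0.031 with thinned cells), Pfkl (-0.76) and Hk2 (-0.63), and Vegfa (1.06) and Il10 (-0.83).

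**Figure D3:**
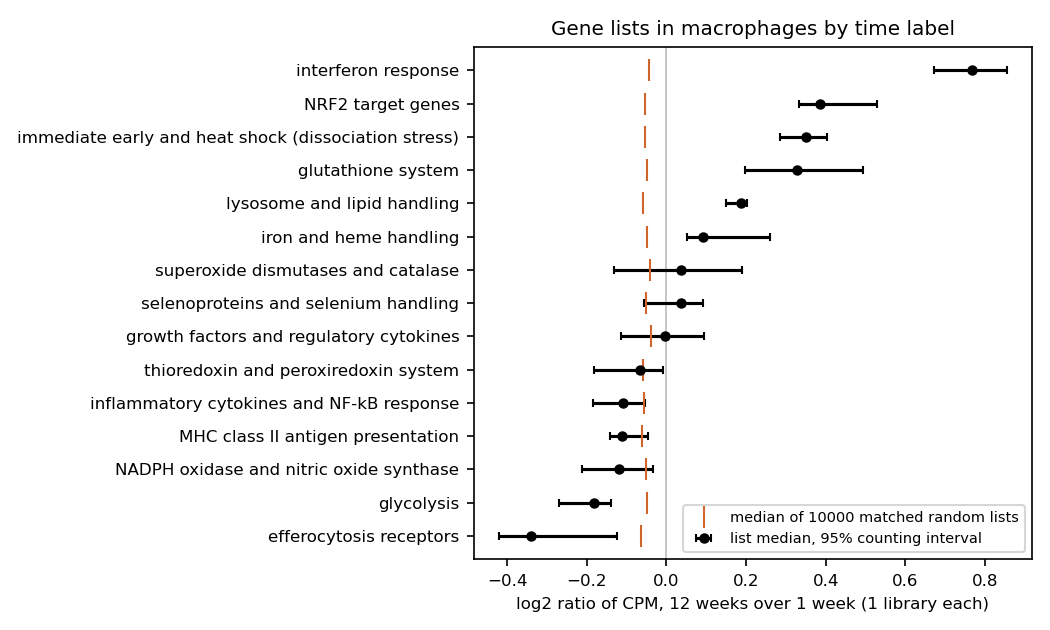
Median log2 ratio of CPM in macrophages, 12 weeks over 1 week, for each fixed list (points, 95% counting intervals), with a mark at the median of 10000 matched random lists. Interferon response (0.77) and NRF2 target genes (0.38) lay furthest to the right, and efferocytosis receptors (-0.34) furthest to the left.

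Of 7791 genes with at least 100 UMIs, the median log2 ratio was -0.06, and 0.00 with TMM scaling and -0.10 with the mean of per-cell CPM. Among the 10 highest were Retnlg, S100a8, S100a9, Hist1h2ap, Hist2h2aa1, Ctla2a, Hbb-bs, Dnaja4 and Ctla2b, from 5.91 to 2.43. Among the 10 lowest were Lepr, Txndc16, Pclaf, Zfp512, Yae1d1, Wnt4, Ccnb1ip1, Tk1 and Phkg1, from -3.84 to -2.20. Many rested on few cells. The neutrophil genes Retnlg, S100a8 and S100a9 had 50% of their 12-week UMIs in 3 cells, and a single cell held 94.8% of those of the hemoglobin gene Hbb-bs. A single 1-week cell held 78.4% of Lepr, 85.6% of Txndc16 and 79.3% of Phkg1. With each library clustered alone Retnlg, S100a8 and S100a9 had ratios of -1.01, -3.09 and -3.69, and without subset 5 Txndc16, Zfp512 and Phkg1 had 0.13, 0.54 and 0.48. With the same mix of subsets Pclaf reversed to 0.27 and Tk1 had -0.71.

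The last comparison set endocrine hormone transcripts side by side between classes. Ins1 and Ins2, the insulin genes, gave a median of 6 UMIs per macrophage in both libraries, against 5 and 3 in B-like, 4 and 4 in T-like and 5 and 5 in dendritic-like cells, which should lack them. A UMI of either was present in 97.1% and 97.8% of macrophages and in 96.8% to 100% of the other immune cells, and 1-week and 12-week macrophages had median depths of 7247 and 6844 UMIs against 9893 and 3127 for B-like cells. Thinned to 2000 UMIs, the shares were 79.7% and 79.4% in macrophages and 65.9% and 76.9% in B-like cells. The mean was further apart, with 30.5 (30.2 to 30.9) and 12.0 (11.9 to 12.2) UMIs per macrophage against 14.6 and 3.68 per B-like and 7.90 and 8.46 per T-like cell. Hormone transcripts made up 0.373% (0.370 to 0.377) and 0.190% (0.187 to 0.192) of macrophage UMIs, 0.125% and 0.0973% in B-like, 0.142% and 0.126% in T-like and 0.0602% and 0.0806% in dendritic-like cells. Hormone and exocrine enzyme transcripts together made up 0.374% and 0.190% of macrophage UMIs. In endocrine-like cells, which the Epcam gate should have removed, hormone transcripts made up 64.7% and 50.5%. In T-like cells of the 1-week library the share was 0.0535% under the stricter cell filters.

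**Figure D4:**
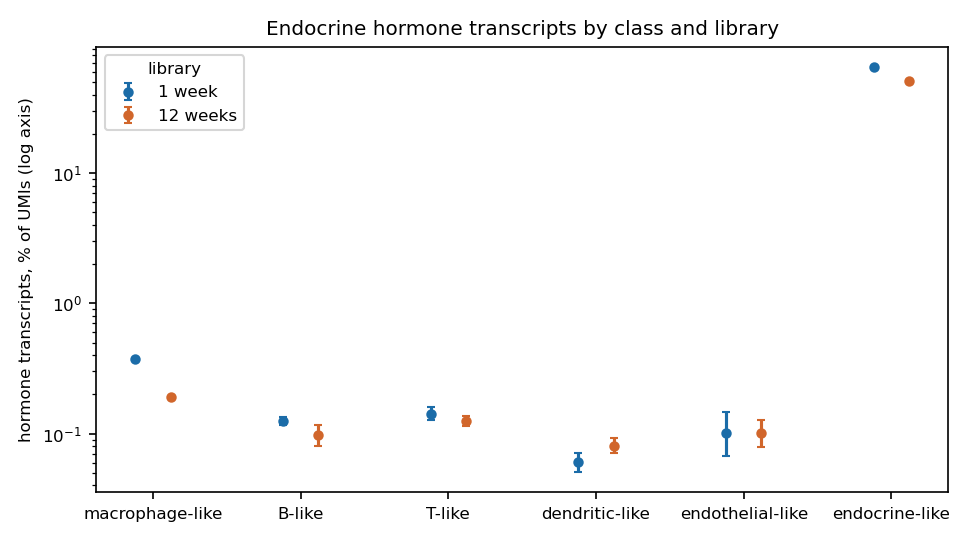
Share of UMIs from hormone transcripts (vertical log axis, percent) by class and library, with exact 95% intervals for counting error only. Macrophages stood at 0.373% and 0.190%, above the other immune classes and below the endocrine-like cells at 64.7% and 50.5%.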

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

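The tests of explanations given here were written down before their results were seen, except the stress values in cells with under 5 C1q UMIs and with the same mix of subsets, the insulin fold at matched depth, and the split by direction and the same class mix for the genes furthest apart, which were added afterwards.

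Sod1 had log2 fold changes between macrophages and the other immune classes of opposite sign in the libraries, 0.11 in the 12-week library alone and -0.0184 in the 1-week library alone. The difference was not tested, and both values are close to 0.

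Droplets with transcripts of cells outside the immune classes passed the sort. The 1-week library held 31 endocrine-like and 5 endothelial-like cells, and the 12-week library 8 and 10. Of the endothelial-like cells, 3 at 1 week and 8 at 12 weeks held at least 5 UMIs of C1qa, C1qb and C1qc. Of the endocrine-like cells 6 and 1 did, so some of both may be mixed droplets. Neither class entered a comparison of gene expression between immune classes.

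Stress genes stood higher in macrophages of the 12-week library (median log2 ratio 0.35). Handling stress shared by every cell type was weighed against it. The mean of the medians in B-, T- and dendritic-like cells was -0.69 (counting half-width 0.144), on the other side of 0. It rested mostly on B-like cells (-1.84), with -0.11 (-0.30 to 0.07) in T-like and -0.14 (-0.45 to 0.03) in dendritic-like cells. Cells with at least 5 C1q UMIs were more common at 1 week, with 36.6% of B-like cells against 6.45% at 12 weeks. Their macrophage transcripts can lower the values over all cells. In cells with under 5 C1q UMIs the mean was -0.53, from -0.69 (-1.30 to -0.14), -0.74 (-0.99 to -0.24) and -0.16 (-0.39 to 0.18). No class median was above 0, which argues against such a shared cause, although some of the intervals held 0. Subsets 2 and 4, with heat shock genes among their leading genes, held 210 and 68 of 1220 macrophages at 1 week and 430 and 352 of 1609 at 12 weeks, and with the same mix of subsets the median was 0.14. A stress specific to macrophages, a library difference and the time label itself stay open, since each time label has 1 library.

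Insulin transcripts were more numerous in macrophages than in B- and T-like cells. Free islet RNA in every droplet would keep the fold near 1. The fold over the higher of those classes was 2.09 at 1 week and 1.42 at 12 weeks, and 1.795 and 1.498 with cells thinned to the same UMIs, so the bound of 2 was passed in a single library and in none at matched depth. At least 5 C1q UMIs were found in 36.6% of B-like and 50% of T-like cells at 1 week, and in 6.45% and 28.6% at 12 weeks. Macrophage RNA in these cells can pull the fold toward 1. Dendritic-like cells, with lower hormone shares, were not part of this fold. Doublets of a macrophage and an endocrine cell would put most insulin UMIs in few cells, and the 5% of macrophages with most held 67.1% at 1 week and 42.6% at 12 weeks. Free RNA and doublets do not exclude each other, and their parts cannot be told apart here, because neither bound was met in both libraries. No biological explanation was tested.

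The genes furthest apart between the time labels may include a difference of the libraries shared by every cell type. Of the 20 named genes 6 had enough UMIs in B-, T- and dendritic-like cells with under 5 C1q UMIs, with a median signed log2 ratio of 2.14 (1.32 to 2.67) there, but they split by direction, so this median decides nothing for the whole set. The 4 genes higher at 12 weeks, among them Hist1h2ap, Ctla2a and Ctla2b, had 2.40 (1.90 to 3.09) there against 2.84 in macrophages. With the same mix of B-, T- and dendritic-like cells in both libraries they had 1.72 (1.33 to 2.83). These values go with a shared difference for these genes, but the genes are few and Ctla2a is a leading gene of T-like cells. In 12-week macrophages 50% of the UMIs of Hist1h2ap, Ctla2a and Ctla2b lay in 4, 10 and 109 cells. Ctla2b had 3 UMIs at 1 week and 22 at 12 weeks in the other classes. The 2 lower genes, Txndc16 and Yae1d1, had a signed median of -1.22 there, but they are few, and 50% of their 1-week macrophage UMIs lay in 1 and 3 cells, so they decide nothing. The lower genes, those not measured and the time label as the origin stay open.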

How the results depend on the processing

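Settings chosen only after the data were seen were the removal of the highest doublet scores, of mixed droplets and of subset 5, the same mix of macrophage subsets in both libraries, and the total without Gm42418 and AY036118. Over the summary values 463 comparisons with an alternative kept their call and direction, 78 lost a call or fell by over 1.5 times, 26 gained, 61 moved and 3 reversed. Over the named genes 1169 kept theirs, 164 lost a call, 8 gained, 137 moved and 15 reversed. Except where stated, the cause was not tested. Depth limits the other immune classes most, since B-like cells at 12 weeks gave 127423 UMIs and T-like cells at 1 week 204365, against 10581421 and 11084925 for the macrophage sums.

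Between classes, the counts of 333 higher and 158 lower genes became 6 and 50 with the called doublets kept, a setting that leaves T-like cells out of the fit and where the interferon median gained a call at 1.31. Removing the highest doublet scores left the same 3 classes and gave 432 and 151. Without mixed droplets the counts were 852 and 442. The C1q bound of 5 UMIs and the 10 cells needed per profile were set after C1q counts were seen, and selecting on macrophage transcripts favours larger folds by construction. Glutathione lost its call there at 1.86, and MHC class II (1.79), growth factors (4.96) and interferon response (3.13) gained theirs. Without a count filter 1004 genes were higher, and calls were lost for glutathione (0.91), iron and heme (1.41), efferocytosis (1.67), inflammatory (2.02) and stress genes (1.35). DESeq2 called 247 lower. With libraries clustered alone, where B-like cells were the sole comparison class, calls were gained for superoxide dismutases and catalase (1.32), MHC class II (1.04), growth factors (1.19) and interferon response (1.28), and Bhlhe41 reversed to -0.31. An estimated correlation ended the calls of glutathione (median 1.05), NRF2 (1.31), iron and heme (1.404), lysosome (1.48), efferocytosis (1.83), inflammatory (1.84) and stress genes (1.16), whose medians it does not touch. The stricter cell filters left 1 class with 20 cells per library and could not be fitted.

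With 1 library left out at a time, class medians ranged from 0.70 to 1.77 for glutathione, 0.70 to 2.13 for NRF2, 0.079 to 0.32 for selenoproteins, 0.86 to 2.38 for iron and heme, 0.54 to 1.10 for MHC class II, 1.47 to 3.54 for efferocytosis, 0.83 to 3.44 for growth factors, 0.23 to 0.46 for glycolysis, 1.16 to 3.44 for inflammatory, 0.38 to 3.47 for interferon and 0.51 to 2.89 for stress genes. In subset 2 they ranged from -0.25 to -0.17 for NADPH oxidase and -0.24 to -0.12 for MHC class II. Sod1 between classes ranged from -0.018 to 0.11. These carry no test.

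Between subsets, the library block decided most calls. With no replicate block, higher and lower list genes were 0 and 0 in subset 1, 7 and 1 in subset 2, 1 higher in subset 3, 1 and 0 in subset 4, 5 and 0 in subset 6, and 1 and 4 in subset 7. Of the 5 list calls 1 remained, and calls ended for NRF2 (0.43), NADPH oxidase (-0.26) and MHC class II (-0.15) in subset 2 and the thioredoxin system (0.42) in subset 4. An estimated correlation ended all 5, leaving 0, with medians in subset 2 of 0.44, -0.27 and -0.15 and in subset 4 of 0.42 and 0.43. DESeq2 gave 2 higher and 8 lower in subset 1, 8 and 2 in subset 3, 8 higher in subset 6, 16 higher in subset 7 and 8 called lists. Without a count filter 7 were lower in subset 2 and 6 in subset 6, 9 lists were called, and NRF2 in subset 2 lost its call (0.43).

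Subsets were matched to the nearest subset of each reclustering, with an overlap of cells (Jaccard index) from 0.03 for subset 7 to 0.91 for subset 5. Subsets 2 and 4 shared their nearest cluster under the stricter cell filters and the lower resolution, where subset 4 had no match of its own. With doublets kept, 6 were lower in subset 2, 4 higher in subset 3, 7 higher in subset 6 and 3 lists called, and the calls for NRF2 (0.40), NADPH oxidase (-0.34) and MHC class II (-0.052) in subset 2 and thioredoxin (0.24) in subset 4 ended. The stricter cell filters gave 17 and 20 in subset 1, 4 and 4 in subset 3, 5 and 7 in subset 6 and 2 lists, without calls in subset 2 for NRF2 (0.24), NADPH oxidase (-0.19) and MHC class II (-0.051). The lower resolution gave 3 and 0 in subset 1, 32 and 2 in subset 2, 5 and 0 in subset 6 and 3 lists. In subset 2 NADPH oxidase lost its call (-0.0087) and MHC class II reversed (0.29). The higher resolution gave 11 higher in subset 1, 6 lower in subset 2, 9 and 2 in subset 3, 1 lower in subset 6, and 26 and 0 in subset 7. Calls ended for NADPH oxidase (-0.26) and MHC class II (-0.068) in subset 2 and thioredoxin (0.28) in subset 4. Prdx1 (0.073), Spic (0.70), Srxn1 (0.16) and Txnrd1 (0.29) reversed in subset 7. Removing the highest doublet scores left 0 lower in subset 1, 2 lower in subset 2, 11 higher in subset 4 and 0 lower in subset 6, and ended the calls for NRF2 (0.29), NADPH oxidase (-0.22) and MHC class II (-0.0038) in subset 2 and thioredoxin (0.29) in subset 4.

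By time label, TMM scaling gave medians of -0.0029 for thioredoxin, 0.10 for selenoproteins, 0.25 for lysosome, -0.12 for glycolysis, -0.046 for inflammatory and 0.41 for stress genes. The mean of per-cell CPM gave 0.0096 for thioredoxin, a reversal near 0, -0.43 for efferocytosis, -0.053 for inflammatory and 0.083 for stress genes. Thinned cells gave -0.10 for glycolysis, 0.64 for interferon and 0.13 for stress genes, and reversed Rac2 (0.031) and Mertk (-0.38). Without subset 5 the lysosome (0.13), glycolysis (-0.10) and stress (0.42) medians moved, and Txndc16 (0.13), Zfp512 (0.54) and Phkg1 (0.48) reversed. The lysosome median was 0.21 without Gm42418 and AY036118 in the total and 0.22 with libraries clustered alone, where Retnlg (-1.01), S100a8 (-3.09) and S100a9 (-3.69) reversed. With the same mix of subsets the medians were 0.31 for NRF2, 0.0055 for NADPH oxidase, a reversal near 0, 0.15 for lysosome, -0.10 for glycolysis, -0.27 for inflammatory and 0.14 for stress genes, and Pclaf reversed (0.27). The subsets were built from expression, so equal weights can take out part of a difference between the libraries. Under the other settings the NRF2 median stayed within its counting interval, and the glutathione median did so under all.

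Shares moved under the stricter cell filters to 0.870% T-like and 92.6% macrophage-like at 1 week and 0.456% B-like, 1.82% T-like and 95.4% macrophage-like at 12 weeks. With libraries clustered alone they were 0% dendritic-like (no such cluster formed) and 93.1% macrophage-like at 1 week, and 3.03% dendritic-like, 2.51% endocrine-like and 88.9% macrophage-like at 12 weeks. Dendritic-like cells at 12 weeks made up 3.103% without the highest doublet scores. Hormone shares under the stricter filters were 0.356% and 0.181% in macrophages at 1 and 12 weeks, 0.0893% in B-like and 0.0535% in T-like cells at 1 week. Thinned cells gave 0.353% and 0.206% in macrophages, 0.191% in B-like and 0.125% in T-like cells at 1 week.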

Other observations

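The values here were chosen after the data were seen, and no test was attached to them.

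Macrophage subset 5 was led by AL732506.1, Ccnb1ip1, AC160336.1, Tubb5 and Polr2l and came almost wholly from the 1-week library, with 209 cells against 19. Its median of 4566 UMIs per cell lay below that of subsets 1 to 4 and 6. A subset found mostly in a single library cannot be separated from that library.

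Within cells with under 5 C1q UMIs, NRF2 target genes had a median log2 ratio of 12 weeks over 1 week of -0.10 (-0.72 to 0.07) over 6 genes in B-like cells and of 0.94 (0.20 to 1.18) over 7 genes in T-like cells. In dendritic-like cells it was -0.08 (-0.27 to 0.19) over 12 genes. Over all cells of these classes, where macrophage transcripts were more common at 1 week, the medians were -2.002, -0.34 and -0.32. The transcripts Gm42418 and AY036118 made up 2.60% of macrophage UMIs at 1 week and 4.37% at 12 weeks.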
